A study of Homo sapiens with 22 samples.

How the data were processed

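RNA-seq was measured in 20 libraries of the H9 embryonic stem cell line with inducible PAX7, made from 100 ng of RNA each by the LM-Seq method. PAX7 ChIP-seq was made from 20 µg of chromatin at day 23, with 1 ChIP and 1 input library. For expression, the authors aligned reads with Bowtie 0.12.9 and estimated abundance with RSEM 1.2.3 after base calling with CASAVA 1.8.2, and the deposited values are TPM, from which the authors removed mitochondrial genes before rescaling. The sum of each library lay within 1.28 of the nominal TPM total. For ChIP-seq, the authors aligned reads with Bowtie2 and called peaks with MACS 1.0.1, and the deposited score of each peak is as the authors' peak caller gave it. The scale of that score, the control and the threshold are not given in the sources used here, so the score serves for ranking alone. Peak names run to 36889 and 2045 numbers are absent from the list. Sequence names in the peak file are those of GRCh38. Depth per library is unknown from TPM, so no counting error could be given, and precision rests on the 3 to 5 libraries per group.

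Genes with TPM of at least 1 in at least 3 libraries were tested, 15191 of 19084 genes. The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend) on log2(TPM + 1), with all 20 libraries in 1 fit of group means, so that the groups share 1 estimate of the spread per gene. All limma tests were two-sided. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 within each of 6 comparisons, and fold changes are differences of mean log2(TPM + 1). The comparisons were induction at day 14, induction at day 23, the difference between these effects, PAX7+ cells over time, untreated cells over time, and myocytes against PAX7+ cells of day 23. Groups were taken from the sample labels. Replicate numbers could mean shared differentiations, so this was checked from correlations of library residuals. At day 14 libraries of the same number correlated at r = 0.211 to 0.356 and each of 4 untreated libraries correlated best with its own number. Of the 4 PAX7+ libraries 3 did, and replicate 2 correlated higher with untreated replicate 1 (r = 0.266). In the other comparisons same-number correlations reached at most 0.144. The replicate number as a block was run as an alternative.

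Named genes followed a rule fixed before the files were opened: PAX7 and the surface proteins in the induction comparisons, and in each comparison the 12 highest and 12 lowest log2 changes among called genes with a mean TPM of at least 5 in the higher group and no overlap between groups, without clone or locus names. Members of fixed lists could be named as well. The 30 lists, also fixed then, cover myogenic regulators, satellite cell markers, the surface proteins, sarcomere, excitation-contraction, fusion, presomitic, sclerotome, pluripotency, neural, neural crest, endothelial, blood, cardiac, smooth muscle, fibroblast, endoderm, epithelial, kidney, cell cycle, cell cycle inhibitor, Notch, Wnt, BMP, FGF, immediate early, ATF4, interferon and anterior and posterior HOX genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with the correlation estimated from the data. Counts adjusted over the list alone used the p-values of list members only.

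Overlaps of calls and shares of genes near peaks were compared by two-sided Fisher's exact tests in R and in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. Gene positions came from RefSeq on GRCh38, matched by symbol for 13658 genes and by an older name for 1420, with 113 unmatched, and 15074 lay on autosomes or X. A test around transcription starts had been planned, but the gene table used here has no strand, so a peak centre inside the gene or within 50 kb of either end was used in its place, a choice made after the files were opened. Motifs of PAX7 in peaks were not analysed here because no genome sequence was used.

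Alternatives were pseudocounts of 0.1 and 5, other filters on low values, median-ratio scaling, quantile normalization, a fit of the compared groups alone, robust eBayes, array weights, a 2-fold minimum, the replicate block and leaving out each library. For peaks they were windows of 5, 10 and 100 kb, peaks above the median score, and comparison genes matched on expression. Added after the files were opened were the removal of 9 MTRNR2L genes, gene-length matching, peaks inside genes and the overlap without 1 library. On simulated data with 200 changed genes, the fit recovered 50.7% to 63.7% of 2-fold and 86% to 90% of 4-fold changes in the comparisons of groups, and 29.3% and 70.3% for the difference of effects, with 5.67 to 13 false calls per simulation. The list moved in the simulation was called in 3 of 3 simulations and no other list was. Genes varied independently in these simulations, so they could not show false list calls that arise where genes of a list are correlated. All 1000 simulated peaks were assigned to their gene and 0 distant peaks were.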

Results

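Gene expression was measured by RNA-seq in 20 libraries of H9, an established human embryonic stem cell line, carrying a doxycycline-inducible PAX7 gene. PAX7 is a paired-box transcription factor of muscle progenitors and adult muscle stem cells. The cells went through embryoid bodies towards skeletal muscle and were sampled in 5 groups. At day 14, 4 libraries came from unsorted mesoderm cells without doxycycline and 4 from GFP-sorted cells given 1 µg/ml doxycycline from day 10. At day 23, 3 libraries came from unsorted proliferating cells without doxycycline and 5 from GFP-sorted proliferating cells with it. The remaining 4 libraries came from myocytes at day 30, 7 days after doxycycline was withdrawn. They are labelled as GFP+ cells, and at which day these were sorted is unclear from the labels. A PAX7 ChIP-seq library and 1 input library were made from doxycycline-treated cells at day 23. The comparisons ask which genes differed with PAX7 induction at each stage, which changed as the cells matured and differentiated, and where PAX7 was bound.

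Values are TPM, transcript abundances scaled for gene length and library size. They are given as mean ± SD over the libraries of a group, with n = 4 for the 2 groups of day 14, n = 3 for untreated and n = 5 for PAX7+ cells of day 23, and n = 4 for myocytes. Sequencing depth is unknown because the deposited values are TPM. Each library listed between 14175 and 15261 genes above 0. Across genes, log2 levels of library pairs within a group correlated at r = 0.877 to 0.979, and the lowest value was within the untreated day-23 group. The first principal component held 41.8% of the variance and the second 19.6%. The replicates are called biological in the design text, which does not say that they came from separate differentiations, so p-values measure the spread between these libraries. Treated cells were given doxycycline and sorted for GFP, and untreated cells were neither. In both induction comparisons induction, exposure to doxycycline and sorting therefore cannot be separated.

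**Figure D1:**
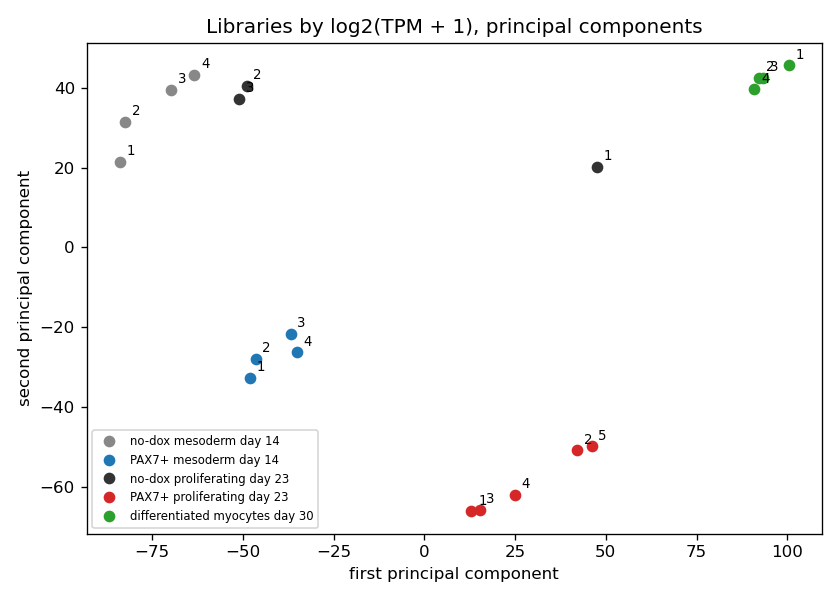
The 20 libraries are placed by their scores on the first principal component (x axis, 41.8% of the variance) and the second (y axis, 19.6%) of log2(TPM + 1), with colour for the 5 groups and the replicate number beside each point. Replicate 1 of the untreated day-23 cells lies apart from replicates 2 and 3 of its group.

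PAX7 itself separated induced from uninduced libraries. It stood at 2360 ± 616 TPM in sorted PAX7+ mesoderm cells (range 1830 to 3186, n = 4) and at 5.79 ± 2.32 TPM in untreated ones (n = 4). At day 23 it stood at 2194 ± 281 TPM in PAX7+ cells (range 1916 to 2642, n = 5) and at 2.28 ± 0.1 TPM in untreated cells (n = 3). In myocytes, 7 days after doxycycline withdrawal, it was 9.14 ± 10.4 TPM (range 3.57 to 24.7, n = 4). The changes were 8.47 log2 units at day 14 (SE 0.38, limma adjusted p 3.846e-11), 9.38 at day 23 and −8.19 from day 23 to day 30. Transcripts of the transgene and of the endogenous gene are not told apart in a gene-level value.

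At day 14 large increases after PAX7 were in MUSTN1, a small protein expressed in muscle and bone, which rose from 1.27 ± 1.09 to 207 ± 91.4 TPM, and in SOSTDC1. The latter, a secreted antagonist of BMP and Wnt signalling, rose from 1.53 ± 0.957 to 137 ± 21.1 TPM. PPP1R14C, an inhibitor of protein phosphatase 1, rose from 1.78 ± 0.922 to 116 ± 35.8 TPM, and DLK1, an imprinted membrane protein related to Notch ligands, from 8.85 ± 5.83 to 145 ± 36.4 TPM. Decreases included SPP1, which encodes the secreted protein osteopontin and fell from 252 ± 102 to 11.3 ± 4.49 TPM. ACTA1, skeletal muscle actin, fell from 96.0 ± 49.8 to 9.93 ± 5.97 TPM. On the log2(TPM + 1) scale these changes were 6.56, 5.83, 5.42, 4.08, −4.34 and −3.14, with standard errors of 0.31 to 0.55 and limma adjusted p from 5.954e-04 down to 1.291e-08. None of these genes overlapped between the groups in any library, which the naming rule requires of the genes it selects, so this adds no support. In all, 2255 genes rose and 827 fell among 15191 tested, and 950 and 527 of them changed at least 2-fold. The share of increases depended on scaling: it was 73.2% on TPM, 49.6% of 2793 calls after median-ratio scaling (1384 higher, 1409 lower) and 60.3% of 2799 after quantile normalization, and median-ratio scaling moved the median of all genes from 0.10 to −0.05 log2 units.

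Pluripotency genes were lower in the sorted PAX7+ cells at day 14. Of 15 tested, 6 fell and none rose, or 9 when adjusted over the list alone. NANOG, a core pluripotency factor, fell from 142 ± 60.3 to 21.4 ± 4.13 TPM and DPPA4 from 707 ± 224 to 195 ± 34.3 TPM (log2 changes −2.60 and −1.81). None of 14 epithelial genes passed the test. EPCAM, an epithelial adhesion protein also carried by embryonic stem cells, stood at 694 ± 79.1 TPM in untreated and 650.2 ± 143 TPM in PAX7+ cells. Of 14 neural genes 6 fell (9 adjusted over the list alone), among them INA, a neurofilament protein, from 25.1 ± 17.7 to 5.62 ± 1.75 TPM. Of 11 endothelial genes 4 fell (5 adjusted over the list alone), with KDR, a VEGF receptor, going from 55.0 ± 31.9 to 7.08 ± 3.61 TPM. Among 24 fibroblast and matrix genes 5 fell, in both adjustments, including COL1A1, from 619.9 ± 285 to 138 ± 9.09 TPM. ATF4 and integrated stress targets had 7 members down and 1 up of 16 (11 and 2 adjusted over the list alone), with GDF15, a stress-responsive secreted factor, falling from 67.7 ± 28.2 to 11.6 ± 9.28 TPM. These 5 lists passed camera with a preset correlation (adjusted p 1.152e-05, 3.234e-05, 0.00424, 3.044e-04 and 1.874e-04), but with an estimated correlation none did (adjusted p 0.630, 0.0858, 0.173, 0.639 and 0.173). Without replicate 4 of the untreated cells the fibroblast list had an adjusted p of 0.0767.

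A smaller number of muscle and signalling genes rose at day 14. Among 18 myogenic regulators 3 rose, in both adjustments: MEOX1, a somite homeobox factor, from 6.41 ± 6.16 to 38.4 ± 13.3 TPM, MEF2C, a muscle transcription factor, from 0.723 ± 0.405 to 8.79 ± 1.83 TPM, and MEF2A. NOTCH2, a Notch receptor, rose from 49.0 ± 7.07 to 231 ± 28.1 TPM, among 17 Notch pathway genes of which 3 rose and 1 fell (4 and 3 adjusted over the list alone). Of 12 BMP targets 3 rose, with SMAD9, a BMP signal transducer, at 19.1 ± 6.27 against 3.28 ± 1.99 TPM. Of 16 interferon-stimulated genes 4 rose (5 adjusted over the list alone). NCAM1, a neural and muscle adhesion protein, and DLK1 were the 2 risers among 23 satellite cell and muscle progenitor markers, of which 1 fell. Of 45 sarcomere genes 2 rose and 3 fell (2 and 2 adjusted over the list alone), and of 22 excitation-contraction and synapse genes 2 fell (1 adjusted over the list alone). Smooth muscle genes went both ways, with TAGLN and CNN1, actin-binding proteins of contractile cells, among 4 that fell and LMOD1 among 2 that rose, of 13. The myogenic, Notch, BMP, interferon, satellite cell and smooth muscle lists did not pass camera (adjusted p 0.348, 0.776, 0.743, 0.181, 0.885 and 0.0628). The sarcomere and excitation-contraction lists did, downwards (0.00522 and 0.0174), and not with an estimated correlation (adjusted p 0.734 and 0.643). The endoderm list did likewise, with 1 of 10 lower and none adjusted over the list alone (0.0102 and an adjusted p of 0.639 with an estimated correlation). After median-ratio scaling these 3 lists had an adjusted p of 0.0919, 0.146 and 0.0707, and without replicate 4 of the untreated cells the endoderm list had 0.134.

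At day 23, PAX7+ cells again held far more SOSTDC1, at 207 ± 57.2 against 0.317 ± 0.548 TPM. HOXC13, the most 5′ gene of the HOXC cluster, stood at 59.7 ± 24.4 against 0.167 ± 0.289 TPM. FAM101A stood at 346 ± 138 TPM and was listed at 0 in each of the 3 untreated libraries. SPP1 fell from 288 ± 39.4 to 0.534 ± 0.528 TPM and the cartilage link protein gene HAPLN1 from 372 ± 153 to 1.34 ± 0.813 TPM. Decreases also included the keratin gene KRT19 from 736 ± 560.4 to 10.3 ± 6.92 TPM and FST, the activin antagonist follistatin, from 136 ± 85.4 to 1.87 ± 1.60 TPM. The log2 changes of SOSTDC1, HOXC13, SPP1, HAPLN1, KRT19 and FST were 7.34, 5.65, −7.62, −7.32, −5.75 and −5.45, with standard errors of 0.32 to 1.12 and limma adjusted p of at most 1.212e-04. In total 1807 genes rose and 1568 fell of 15191, with 876 and 1066 of them changed at least 2-fold. Increases were 53.5% of the calls on TPM, 44.6% after median-ratio scaling (1468 higher, 1823 lower) and 53.0% after quantile normalization. Single untreated libraries moved this total: it was 4405 without replicate 1 and 2048 without replicate 2. The fit moved it further, to 1919 with only the 2 groups in the fit and 7002 with array weights. Replicate 1 of the untreated cells differed from the others of its group, with POU5F1, a core pluripotency factor, at 16.3 TPM against 687 and 936 TPM, and COL1A1 at 8019 against 1304 and 1538 TPM, while its PAX7 level was 2.18 TPM.

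Epithelial genes were the group most uniformly lower in PAX7+ cells at day 23. Of 14 tested 12 fell (13 adjusted over the list alone). CDH1, the epithelial cadherin, fell from 303 ± 250.4 to 8.46 ± 2.95 TPM, EPCAM from 402 ± 281 to 23.8 ± 3.90 TPM and ESRP1, an epithelial splicing regulator, from 56.2 ± 42.3 to 1.33 ± 0.173 TPM. Pluripotency genes fell in 10 of 15 cases, in both adjustments, with DPPA4 going from 349.7 ± 214 to 61.5 ± 11.2 TPM and SOX2 listed at 0 in all 5 PAX7+ libraries. Of 24 fibroblast and matrix genes 13 fell (16 down and 1 up adjusted over the list alone), such as the collagen gene COL1A2, from 3058 ± 1765 to 304 ± 203 TPM, and POSTN, which encodes periostin, from 234 ± 204 to 2.88 ± 3.58 TPM. Among 16 ATF4 and integrated stress targets 11 fell and 1 rose (12 and 2 adjusted over the list alone), and among 14 neural genes 8 fell (8 down and 1 up adjusted over the list alone). Cardiac, endoderm, Wnt target and anterior HOX lists had 4 of 13, 4 of 10, 5 of 13 and 4 of 9 members lower (6, 6, 7 and 5 adjusted over the list alone) and none higher. All of these lists passed camera downwards, with adjusted p from 1.462e-11 for epithelial to 0.0296 for anterior HOX genes. None did with an estimated correlation (adjusted p 0.110 for the epithelial, neural and stress lists, 0.438 for pluripotency, fibroblast, cardiac, endoderm and anterior HOX genes, 0.451 for Wnt targets). Wnt targets no longer passed without replicate 2 or 3 of the untreated cells (adjusted p 0.0561 and 0.0774), and anterior HOX genes without replicate 3 (adjusted p 0.0774). In replicate 1 of the untreated cells every one of 14 pluripotency and 13 epithelial genes lay below both other replicates, 9 of 10 cardiac and 10 of 11 Wnt target genes did too, and 13 of 22 fibroblast genes lay above both.

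Muscle regulators and posterior HOX genes were higher in PAX7+ cells at day 23. Of 18 myogenic regulators 7 rose and 2 fell, in both adjustments. MYOD1, the myogenic determination factor, stood at 12.4 ± 4.41 TPM and was listed at 0 in the 3 untreated libraries. MEF2C rose from 4.86 ± 3.45 to 46.3 ± 22.6 TPM and PITX3, a homeobox factor of muscle and dopamine neurons, from 0.143 ± 0.248 to 13.8 ± 5.56 TPM. CDH15, the muscle cadherin and a satellite cell and fusion marker, rose from 0.84 ± 0.728 to 20.7 ± 6.62 TPM. MYOG, the myogenin gene, spread from 0 to 64.8 TPM among the 5 PAX7+ libraries. Its call (log2 change 3.35, adjusted p 0.0145) was lost with the replicate number as a block (adjusted p 0.0595), with only the 2 groups in the fit (adjusted p 0.146) and without replicate 2 of the untreated cells (adjusted p 0.0590). Of 16 posterior HOX genes 7 rose and none fell (7 up and 2 down adjusted over the list alone). HOXC11 and HOXC12, both listed at 0 in all untreated libraries, stood at 7.66 ± 1.96 and 18.3 ± 9.73 TPM in PAX7+ cells, and HOXC10 at 6.98 ± 1.71 against 0.44 ± 0.384 TPM. Of 14 fusion genes 4 rose (5 adjusted over the list alone). The myogenic, posterior HOX and fusion lists passed camera (adjusted p 0.0321, 0.0196 and 0.0422), none with an estimated correlation (adjusted p 0.438 for each). With the replicate block the myogenic and fusion lists no longer passed (adjusted p 0.0617 and 0.0571). Leaving out replicate 2 or 3 of the untreated cells or replicate 2 of the PAX7+ cells gave 0.0607, 0.0789 and 0.0821 for the myogenic and 0.116, 0.114 and 0.0878 for the fusion list, which also had 0.0669 without replicate 5 of the PAX7+ cells. Without replicate 1 of the untreated cells the posterior HOX list had 0.0977. Satellite cell markers (7 up, 3 down of 23, or 8 and 5 adjusted over the list alone), excitation-contraction genes (7 up, 2 down of 22, or 7 and 3) and sarcomere genes (5 up, 2 down of 45, or 4 and 2) did not pass camera (adjusted p 0.199, 0.132 and 0.542).

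ICAM1, ITGA9 and SDC2 encode an immunoglobulin-family adhesion protein, an integrin subunit and a heparan sulfate proteoglycan. They were proposed by the study as surface markers from these samples, so their direction here is not independent evidence. SDC2 rose in both comparisons, from 51.6 ± 17.2 to 199 ± 18.3 TPM at day 14 and from 62.8 ± 31.5 to 443 ± 69.1 TPM at day 23 (log2 changes 1.98 and 2.89, limma adjusted p 1.433e-05 and 9.053e-08). ICAM1 rose at day 14, from 7.61 ± 2.26 to 32.2 ± 16.8 TPM (adjusted p 0.0174), a call that ended without replicate 3 or 4 of the PAX7+ cells (adjusted p 0.0530 and 0.0644). At day 23 ICAM1 stood at 109 ± 60.2 TPM in PAX7+ and 57.4 ± 67.2 TPM in untreated cells (adjusted p 0.0676, or 5.964e-04 without replicate 1 of the untreated cells). ITGA9 stood at 12.3 ± 3.20 against 8.85 ± 2.18 TPM at day 14 (adjusted p 0.669). At day 23 it stood at 31.0 ± 6.86 against 8.04 ± 6.98 TPM and was called higher (log2 change 2.50, adjusted p 0.00639, or 0.0731 with only the 2 groups in the fit). Adjusted over the list alone, 2 of the 3 rose at day 14 and all 3 at day 23. The 3 passed camera as a list at day 23 (adjusted p 0.00387) and not with an estimated correlation (adjusted p 0.110).

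Genes that rose with induction at day 14 tended to rise at day 23. Of the 2255 genes higher at day 14, 1004 were also higher at day 23, against 268 for independent lists, and 18 were lower. Of the 827 genes lower at day 14, 414 were also lower at day 23, against 85.4 for independent lists, and 2 were higher. The odds ratios were 12.1 and 11.5 (Fisher's exact test, two-sided, p 5.119e-200 for the decreases), and log2 changes correlated at r = 0.631 and rho = 0.572 across genes, which are not independent replicates. After median-ratio scaling 662 increases and 670 decreases were shared, so which of them were more numerous depended on scaling. The comparisons share no library, but both use the 1 estimate of the spread per gene from all 20 libraries. A gene of small spread is thus more easily called on both days. The numbers for independent lists, the odds ratios and the p-value do not allow for this.

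The effect of induction differed in size between the 2 days for 271 genes, 76 with a higher and 195 with a lower log2 change at day 23 than at day 14. MYOD1, PITX3 and CDH15 had higher log2 changes at day 23 than at day 14, by 2.85 (SE 0.46), 3.81 (SE 0.56) and 3.53 (SE 0.48) log2 units (limma adjusted p 0.00257, 0.00115 and 5.908e-04). None of these genes was called at day 14. Among posterior HOX genes 4 of 16 differed, all with a larger effect at day 23 (7 adjusted over the list alone), HOXC13 by 3.97 log2 units. Of 14 epithelial genes 7 differed in the other direction (11 adjusted over the list alone): CDH1 by −4.21 (SE 0.77), EPCAM by −3.47, GRHL2, an epithelial transcription factor, by −3.75 and ESRP1 by −3.43. Epithelial and posterior HOX lists passed camera (adjusted p 6.896e-13 and 1.065e-06) and not with an estimated correlation (adjusted p 0.236 for both). Excitation-contraction, cell cycle, sarcomere, FGF target and fusion lists passed upwards and interferon-stimulated genes downwards (adjusted p 2.837e-06, 1.455e-05, 9.037e-05, 0.0121, 0.0463 and 0.0188). Of their members 3 of 22, 0 of 30, 0 of 45, 0 of 11 and 1 of 14 had a higher effect at day 23 by limma and 1 of 16 a lower one (4, 0, 0, 0, 1 and 4 adjusted over the list alone, and 8, 1, 6, 2, 3 and 5 at an unadjusted p below 0.05). None of these lists passed with an estimated correlation (adjusted p 0.315, 0.595, 0.523, 0.523, 0.523 and 0.523), and fusion not with the replicate block (adjusted p 0.0663). Without replicate 1 of untreated day 23 the cell cycle list had an adjusted p of 0.453, and without replicate 2 of PAX7+ day 23 the FGF target list had 0.0985. The interferon list had 0.0950 and 0.0610 without replicate 1 of untreated day 14 or day 23, and 0.0689 and 0.0526 without replicate 3 or 4 of PAX7+ day 14. The fusion list lay between 0.0570 and 0.213 without replicate 2 or 4 of untreated day 14, 3 of PAX7+ day 14, 2 or 3 of untreated day 23, or 2 or 5 of PAX7+ day 23. The count of 271 was 143 without replicate 2 and 172 without replicate 1 of untreated day 14, 171 without replicate 2 of PAX7+ day 14, 167 without replicate 2 and 677 without replicate 1 of untreated day 23.

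Between day 14 and day 23 the sorted PAX7+ cells lost epithelial transcripts and gained posterior HOX and cell cycle inhibitor transcripts. CDH1 fell from 479.9 ± 112 to 8.46 ± 2.95 TPM, EPCAM from 650.2 ± 143 to 23.8 ± 3.90 TPM and KRT19 from 401 ± 187 to 10.3 ± 6.92 TPM (log2 changes −5.69, −4.70 and −5.26, SE 0.51, 0.39 and 0.70, limma adjusted p of at most 4.313e-05). In total 12 of 14 epithelial genes fell (13 adjusted over the list alone) and 10 of 15 pluripotency genes (11 adjusted over the list alone), with LIN28A, an RNA-binding pluripotency factor, going from 1233 ± 286 to 87.3 ± 49.3 TPM. Of 16 posterior HOX genes 7 rose, in both adjustments, and of 10 cell cycle inhibitors 4 rose (5 adjusted over the list alone), CDKN2A from 1.91 ± 0.615 to 49.3 ± 33.1 TPM and CDKN1A from 103 ± 54.0 to 498 ± 217 TPM. Matrix genes joined the increases, 8 of 24 (9 adjusted over the list alone), such as COL5A2 from 109 ± 61.5 to 1315 ± 298 TPM. Fusion genes had 7 up and 1 down of 14 and excitation-contraction genes 7 up of 22, in both adjustments, myogenic regulators 6 up and 1 down of 18 (8 and 1 adjusted over the list alone), and FGF targets 3 up of 11. In that order of mention these 9 lists passed camera (adjusted p 3.217e-14, 2.799e-05, 5.531e-05, 5.031e-04, 0.0146, 0.00435, 0.0194, 0.0179 and 0.0195), none with an estimated correlation (adjusted p 0.231, 0.484, 0.274, 0.248, 0.643, 0.320, 0.589, 0.484 and 0.503). The 3 surface proteins proposed by the study passed as a list too, with 2 higher (3 adjusted over the list alone, adjusted p 0.0205, and 0.231 with an estimated correlation). Without replicate 2 of PAX7+ day 23 the fibroblast, excitation-contraction, myogenic and FGF lists had an adjusted p of 0.0526, 0.0514, 0.0548 and 0.149. The total was 1474 genes higher and 1712 lower, 767 and 934 of them at least 2-fold, and it was 2033 without replicate 1 of PAX7+ day 14.

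Untreated cells changed less clearly between day 14 and day 23. ITGA11, a collagen-binding integrin, stood at 101 ± 144 TPM at day 23 against 1.23 ± 1.61 at day 14. FBN1, which encodes fibrillin 1, stood at 157 ± 211 against 8.03 ± 4.52 TPM, and PRRX1, a mesenchymal homeobox factor, at 11.2 ± 7.40 against 0.562 ± 1.03 TPM (log2 changes 4.53, 3.27 and 2.96, limma adjusted p 0.00281, 0.00473 and 0.00233). HES3, a Hes-family repressor, fell from 17.9 ± 13.2 to 1.49 ± 1.35 TPM. Replicate 1 of day 23 carried most of the first 2, with ITGA11 at 267 against 12.2 and 22.8 TPM and FBN1 at 400 against 40.0 and 30.7 TPM, and without it their log2 changes were 3.22 and 2.11 (adjusted p 0.00950 and 0.00787). Of 24 fibroblast and matrix genes 10 rose (15 adjusted over the list alone), 3 of 15 pluripotency genes fell (10 adjusted over the list alone) and 3 of 10 cell cycle inhibitors rose (4 adjusted over the list alone). No cell cycle gene of 30 passed alone, and their median log2 change was −1.13. These 4 lists passed camera (adjusted p 2.712e-06, 4.259e-05, 0.0208 and 1.643e-09). So did epithelial (1 of 14 lower, 6 adjusted over the list alone, 0.0154), Notch (1 of 17 lower, 0 adjusted over the list alone, 0.0490) and anterior HOX genes (2 of 9 higher, 3 adjusted over the list alone, 0.0365). None did with an estimated correlation (adjusted p 0.696 for 6 of them and 0.774 for epithelial), and Notch not with the replicate block (adjusted p 0.0823). The Notch list had 0.121 and 0.0746 without replicate 1 or 4 of day 14 and 0.141 without replicate 2 of day 23, and the epithelial list had 0.0522 without replicate 3 of day 14 and 0.423 without replicate 1 of day 23. The anterior HOX list had 0.0834 and 0.0792 without replicate 1 or 2 of day 14, and 0.0714 and 0.20 without replicate 2 or 3 of day 23. Replicate 1 of day 23 moved with each of these groups: against the mean of the other replicates the median log2 difference was −4.43 for pluripotency, −2.34 for cell cycle, 0.96 for fibroblast and 0.71 for cell cycle inhibitor genes. The total of 1128 genes higher and 449 lower, 639 and 277 of them at least 2-fold, was 99 without that library, 399 and 404 without replicate 1 or 2 of day 14, and 2824 without replicate 3 of day 23. With only these 2 groups in the fit limma called 0 genes, with 2628 at an unadjusted p below 0.05, so ITGA11, FBN1, PRRX1 and HES3 were then not called (adjusted p 0.240 each). The share of increases was 71.5% on TPM, 51.4% after median-ratio scaling (766 higher, 723 lower) and 56.9% after quantile normalization.

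Transcripts of the contractile apparatus were far higher in myocytes than in PAX7+ cells of day 23. The embryonic myosin heavy chain gene MYH3 rose from 5.37 ± 3.72 TPM in PAX7+ cells of day 23 to 3760 ± 1814 TPM in myocytes. The fast myosin light chain genes MYLPF and MYL1 rose from 1.29 ± 0.597 to 1705 ± 656 TPM and from 2.09 ± 2.92 to 1641 ± 915 TPM, and TNNC2, fast troponin C, from 1.62 ± 1.58 to 1164 ± 432 TPM (log2 changes 9.27, 9.47, 9.39 and 8.97, SE 0.39 to 0.65, limma adjusted p of at most 2.838e-09). Of 45 sarcomere genes 43 rose and 1 fell (44 and 1 adjusted over the list alone). The faller was TPM3, a tropomyosin gene also used outside muscle, from 379.9 ± 28.4 to 264 ± 15.2 TPM. Of 22 excitation-contraction and synapse genes 18 rose, in both adjustments, including CACNA1S, the muscle calcium channel subunit, from 0.11 ± 0.116 to 48.2 ± 21.2 TPM, and CHRNA1, the muscle acetylcholine receptor subunit, from 18.5 ± 9.13 to 127 ± 33.5 TPM. MYOG rose from 29.6 ± 28.1 to 234 ± 23.2 TPM (log2 change 4.22, adjusted p 8.158e-04). It was among 9 of 18 myogenic regulators that rose and 2 that fell (11 and 2 adjusted over the list alone), while MYOD1 stood at 12.4 ± 4.41 and 16.7 ± 2.28 TPM (adjusted p 0.279). Of 14 fusion genes 8 rose, in both adjustments, with TMEM8C, the fusion protein myomaker, going from 2.07 ± 2.22 to 79.1 ± 9.47 TPM.

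All 30 cell cycle genes fell, in both adjustments, with MKI67 going from 139 ± 79.0 to 11.6 ± 7.64 TPM and TOP2A, a topoisomerase, from 339 ± 169.6 to 27.0 ± 10.1 TPM (log2 changes −3.44 and −3.49). CDKN2B, a cell cycle inhibitor, rose from 18.8 ± 12.3 to 339 ± 141 TPM. FAM101A fell from 346 ± 138 to 23.0 ± 8.91 TPM and BCOR, a transcriptional corepressor, from 305 ± 113 to 20.1 ± 7.15 TPM. Fibroblast and matrix genes had 14 up and 1 down of 24, in both adjustments, led by COL3A1, from 141 ± 131 to 17782 ± 4687 TPM, and POSTN, to 720.3 ± 199 TPM. Smooth muscle genes had 11 up of 13 (11 up and 1 down adjusted over the list alone), of which DES and TPM2 also belong to the sarcomere list, with SYNPO2, an actin-bundling protein, rising from 2.42 ± 0.381 to 84.8 ± 40.6 TPM. Among 14 neural genes 6 rose, in both adjustments, and NEFM, neurofilament medium chain, rose from 2.78 ± 3.45 to 748 ± 301 TPM. ATF4 and integrated stress targets had 10 up and 1 down of 16, in both adjustments. Cardiac (4 up of 13) and sclerotome genes (6 up and 2 down of 15, 7 and 2 adjusted over the list alone) also passed.

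Sarcomere, excitation-contraction and smooth muscle genes were the lists of day 30 that passed camera both with a preset correlation (adjusted p 1.582e-44, 2.493e-17 and 1.134e-09) and with an estimated one (adjusted p 0.00788, 0.0154 and 0.0376). The other 8 did so with a preset correlation alone (adjusted p 1.945e-16 to 0.0402), and their adjusted p with an estimated correlation was 0.260 for cell cycle, 0.222 for fibroblast, 0.196 for myogenic regulator, 0.0796 for fusion, 0.0830 for stress, 0.0636 for neural, 0.405 for cardiac and 0.294 for sclerotome genes. The sclerotome list did not pass with the replicate block (adjusted p 0.0670), without replicate 3, 4 or 5 of the PAX7+ cells (0.0514, 0.0509 and 0.0635) or without replicate 3 or 4 of the myocytes (0.0535 and 0.0683). The totals were 1921 genes higher and 3007 lower, 1321 and 1157 of them at least 2-fold. Increases were 39.0% of the calls on TPM and 55.0% after median-ratio scaling (2489 higher, 2039 lower), which moved the median of all genes from −0.10 to 0.03 log2 units. Withdrawal of doxycycline, the change of medium and the passage of time coincide in this comparison, and a difference in sorting is not ruled out. Across all comparisons, other splits of the same libraries called as many lists as the real one in at least 5% of cases, so list calls are descriptions of these libraries. Presomitic, neural crest, blood, kidney and immediate early lists passed camera in none of the 6 comparisons, with 4, 1, 1, 0 and 1 members called at day 14, 6, 3, 2, 1 and 0 at day 23 and 3, 6, 1, 3 and 4 at day 30. Satellite cell markers did not pass at day 30 either (10 up and 2 down of 23, or 10 and 4 adjusted over the list alone, adjusted p 0.0713).

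**Figure D2:**
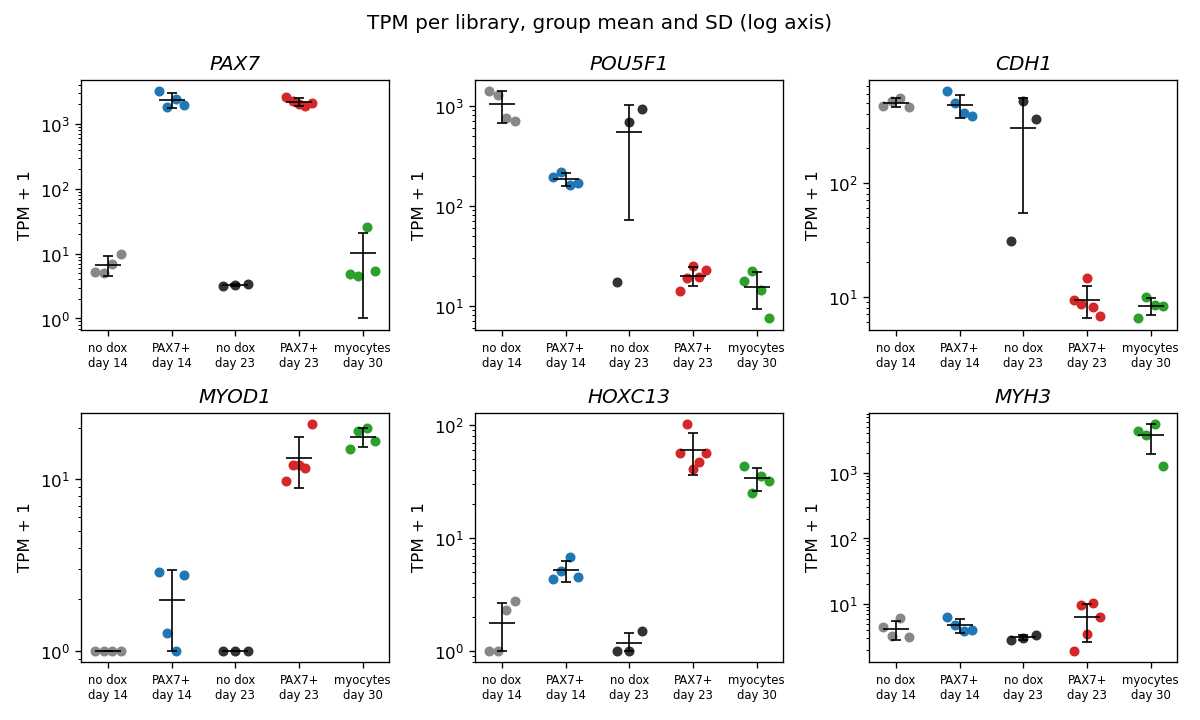
Each panel shows 1 gene, with the 20 libraries as points by group on the x axis, TPM + 1 on a log10 axis and the group mean of TPM as a bar mark with its SD, whose lower arm stops at 0 TPM. PAX7 lies between 1830 and 3186 TPM in the 9 PAX7+ libraries, CDH1 falls in PAX7+ cells between day 14 and day 23, and MYH3 rises in myocytes.

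The single PAX7 ChIP-seq library of day 23 gave 34844 peaks in GRCh38 coordinates, as the authors called them with a control and threshold that the sources used here do not give, 34483 of them on autosomes and X. Their median width was 266 bp (57 to 5128), and the authors' peak score ran from 50 to 1127.2 with a median of 75.61. The peak of highest score lay on chromosome 19 from 3837193 to 3838420, within ZFR2. SDC2 held 5 peaks within the gene, the highest on chromosome 8 from 96579749 to 96580468 (score 171.3), and ITGA9 held 4, the highest on chromosome 3 from 37486104 to 37486389 (144.4). The highest peak within 50 kb of ICAM1 lay on chromosome 19 from 10270890 to 10271256 (103.66). Its centre was 47 bp outside the gene, and the peak itself reached into the gene. SOSTDC1 held 1 peak, on chromosome 7 from 16465448 to 16465911 (108.57). MUSTN1 had its highest peak centred 269 bp outside, on chromosome 3 from 52835111 to 52835465 (186.83). PAX7 itself held 4, the highest on chromosome 1 from 18675938 to 18676396 (194.86). No peak centre lay within 50 kb of MYOD1, HOXC12, HOXC13, POU5F1 or FAM101A. Exon and intron positions of these peaks were not analysed here, and with 1 ChIP library there is no replicate check.

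Genes that rose with PAX7 had a peak nearby more frequently than genes not called. At day 14, 1945 of 2245 genes that rose (86.6%) had a peak centre within the gene or within 50 kb of either end, against 79.5% of 12011 genes not called (odds ratio 1.67, Fisher's exact test, two-sided, p 3.985e-16). At day 23 it was 1535 of 1799 (85.3%) against 79.9% of 11715 (odds ratio 1.46, p 2.839e-08). For genes that fell no difference from genes not called passed the test at this distance, with 642 of 818 (78.5%, odds ratio 0.941, p 0.503) at day 14 and 1238 of 1560 (79.4%, odds ratio 0.967, p 0.614) at day 23. In windows of 5 and 10 kb and inside genes, fewer of the genes that fell at day 14 had a peak (odds ratios 0.762, 0.796 and 0.812, p 2.451e-04, 0.00166 and 0.00686). Inside genes, more of those that fell at day 23 had one (odds ratio 1.19, p 0.00166). Gene length was not matched in these windows. At day 30, both the 1913 genes that rose (83.0%) and the 2995 that fell (84.2%) exceeded the 78.9% of genes not called (odds ratios 1.30 and 1.42, p 3.891e-05 and 9.803e-11). Adjustment over the 6 tests gave 5.837e-05 and 2.941e-10, with 2.391e-15 and 5.677e-08 for the increases of days 14 and 23. Against genes of like length the odds ratios for increases at 50 kb were 1.35 at day 14, 1.31 at day 23 and 1.07 at day 30, the last with p 0.308. Over all tested genes with a position, 80.5% had a peak within this distance, so the measure leaves little room for differences. These tests used the calls on TPM alone. Other scaling, which changed the split of increases and decreases, was not run for them. The peaks were those of day 23, also where set against calls of days 14 and 30.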

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

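The tests of other groupings in this part were chosen after the gene counts had been seen, whereas the comparison of induction effects between days and the search for outlying libraries were chosen before the data were examined. The effect of induction differed between day 14 and day 23 for 271 genes. MYOD1, a myogenic determination factor, PITX3, a homeobox factor, CDH15, the muscle cadherin, and HOXC13 had effects larger at day 23 by 2.85, 3.81, 3.53 and 3.97 log2 units. CDH1 and EPCAM, epithelial adhesion genes, GRHL2, an epithelial transcription factor, and ESRP1, a splicing regulator, had lower effects at day 23, by −4.21, −3.47, −3.75 and −3.43 log2 units. As many genes came from 3 of 100 groupings of the same libraries, the real one included. These groupings shuffle induced and untreated labels within each day, which also breaks the induction effects themselves and the pairing by number at day 14. They do not ask whether the 2 effects are equal, so this share cannot exclude chance for the count. Both other groupings of the 3 gave far more. The highest, with 3561, puts replicate 1 of the untreated day-23 cells among the PAX7+ libraries of that day, and the other, with 1098, regroups the libraries of day 14 alone. The latter leaves the induction effect of day 23 whole, which alone can give a high count. Both counts therefore speak neither for nor against the 271 genes. The count of 271 is weak evidence because single libraries moved it. It was 677 without replicate 1 of untreated day 23 and 167 without replicate 2 of that group. Without replicate 2 or 1 of untreated day 14 it was 143 and 172, and without replicate 2 of PAX7+ day 14 it was 171.

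In groups of 4 or 5 libraries, 160 group values were tested for a single library far from the others of its group. This held for 23 of them, 21 of them gene levels. Chance gives about 1 in 20 for independent and normally distributed values. TPM is skewed to high values and genes of 1 library can move together, so the count cannot be read as an excess over chance. PAX7 stood at 24.7 TPM in replicate 3 of the myocytes, against at most 4.49 in the others. Among PAX7+ cells of day 23, replicate 5 was highest for MYOD1 (20.1 TPM), POSTN (9.12), CDKN2A (106.7), CDKN2B (40.1) and COL5A2 (1829). Replicate 2 of that group was highest for SOX8 (553 TPM, next 80.5), HOXC13 (101.7), RBM47 (121.7), NEFM (8.78) and MYBPH (2.44), and replicate 1 for HOXC12 (35.0). Among PAX7+ cells of day 14, replicate 4 was highest for MEOX1 (58.2 TPM), replicate 2 for MEF2C (11.5) and replicate 3 for CFI (59.1). Among untreated cells of day 14, replicate 4 was highest for ITGA11 (3.62 TPM), FBN1 (14.8) and PRRX1 (2.1), replicate 1 for HES3 (37.6) and replicate 2 lowest for GDF15 (25.5). In myocytes replicate 4 was lowest for CACNA1S, at 16.5 TPM, and in its number of genes above 0, at 14286 against 14873 or more. MTRNR2L genes took 1.21% of TPM in replicate 1 of PAX7+ day 23, against at least 1.91% in the others. No explanation was tested for these libraries.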

How the results depend on the processing

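The removal of MTRNR2L genes, gene-length matching, peaks inside genes and the overlap without 1 library were tests chosen only after the results were seen. Of 129 alternative counts of genes 107 stayed within 1.5 times the count reported, as did 79 of 87 counts of lists. Of 15350 alternative values for single named genes 13751 kept direction and side of the threshold, 1597 kept direction but no longer passed, 2 newly passed and 0 reversed. These genes were entered because they had passed the main test, apart from surface proteins in the induction comparisons. Few could newly pass and a reversal was unlikely, so the counts show only how many calls were lost. Of 762 values for single lists other than with an estimated correlation, 698 kept their call.

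A 2-fold minimum left 1477 genes at day 14, 1942 at day 23, 2478 at day 30, 1701 for PAX7+ and 916 for untreated cells over time, by construction. Array weights gave 7002 genes at day 23, 4840 and 2856 for PAX7+ and untreated cells over time and 1790 for the difference of effects. With only the compared groups in the fit, limma called 1919 genes at day 23 and 0 for untreated cells over time (2628 at an unadjusted p below 0.05). The cause was not tested for these. No gene count moved by over 1.5 times with the replicate block.

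Without 1 library, counts ran from 2048 to 4405 at day 23 (without replicate 2 or 1 of the untreated cells), 2033 to 2875 for PAX7+ cells over time (without replicate 1 of day 14 or of day 23). They ran from 99 to 2824 for untreated cells over time (without replicate 1 or 3 of day 23) and 143 to 677 for the difference of effects (without replicate 2 of untreated day 14 or 1 of untreated day 23). Lists for that difference ran from 6 to 15.

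With an estimated correlation 0 lists passed camera at day 14, day 23, over time in PAX7+ or untreated cells and for the difference of effects, and 3 at day 30. Median-ratio scaling left 5 lists at day 14 and gave 662 shared increases and 670 shared decreases of days 14 and 23. The shared increases were 1184 and decreases 505 without replicate 1 of untreated day 23. By construction 17421 peaks lie above the median score.

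For peaks near genes lower at day 14, odds ratios were 0.762 and 0.796 in windows of 5 and 10 kb and 0.812 for peaks inside genes, past the threshold, and reversed to 1.13 at 100 kb and, at 50 kb, to 1.01 against genes of like length, which were not matched in narrower windows. For genes lower at day 23 they reversed to 1.08 at 5 kb, 1.05 at 10 kb, 1.01 for peaks above the median score and 1.19 inside genes, the last past the threshold (p 0.00166). For genes higher at day 30 gene-length matching gave 1.07, no longer past the threshold. The cause of the reversals was not tested. Motif alternatives were not run. Depth is unknown, so its limits cannot be given.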

Other observations

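All tests of explanations and of other groupings in this part were chosen after the results were seen, and the genes named first follow the rule fixed before the data were examined. ADAMTS5, a matrix protease, rose with induction at day 14 from 0.335 ± 0.191 to 20.9 ± 2.57 TPM, and CFI, complement factor I, from 0.138 ± 0.159 to 34.9 ± 16.3 TPM (n = 4 each, log2 changes 4.04 and 4.90). At day 23 NEURL1B, a ubiquitin ligase of the Notch pathway, rose from 3.24 ± 1.58 to 154 ± 54.7 TPM. SOX8, a transcription factor also used in muscle progenitors, rose from 2.41 ± 1.49 to 169 ± 215 TPM (log2 changes 5.19 and 5.12). Replicate 2 of the PAX7+ cells held 553 TPM of SOX8 and the other 4 between 68.5 and 80.5 TPM, and without it the log2 change was 4.54, still called. PODXL, a surface sialomucin abundant on pluripotent and epithelial cells, fell from 683 ± 531 to 10.0 ± 2.30 TPM. RGS5, a G-protein regulator of pericytes, fell from 64.1 ± 28.8 to 0.974 ± 0.320 TPM (n = 3 and 5, log2 changes −5.26 and −4.93). Between day 14 and day 23 of PAX7+ cells, TMEFF2, a transmembrane protein with follistatin domains, rose from 6.38 ± 3.32 to 124 ± 35.9 TPM and the protease gene HTRA3 from 15.3 ± 9.0 to 224 ± 102 TPM. TRIM71, a repressor of differentiation in stem cells, fell from 97.0 ± 23.3 to 2.96 ± 1.54 TPM.

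In myocytes the calcium store gene CASQ2 rose from 0.17 ± 0.186 to 269 ± 122 TPM and MYBPH, myosin-binding protein H, from 0.606 ± 1.06 to 243 ± 116 TPM (n = 5 and 4, log2 changes 7.73 and 7.27). PBK, a mitotic kinase, fell from 96.2 ± 41.4 to 4.68 ± 3.46 TPM. MYBL2, a cell cycle transcription factor, fell from 200.3 ± 121 to 13.5 ± 9.88 TPM, and RBM47, an RNA-binding protein, from 79.2 ± 24.4 to 3.95 ± 2.07 TPM (log2 changes −4.29, −3.85 and −4.11, limma adjusted p of at most 1.059e-04).

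Replicate 1 of the untreated day-23 cells held less POU5F1, NANOG and LIN28A, at 16.3, 4.99 and 9.16 TPM, than replicates 2 and 3, which held 687 and 936, 111 and 104, and 898 and 1202 TPM. Its smooth muscle genes were higher, with TAGLN at 901 against 294.5 and 294.6 TPM. Across genes its log2 levels correlated best with replicate 5 of the PAX7+ cells of day 23, higher than with either library of its own group (mean r 0.880). A different measure, the correlation of residuals from the group means, was r = 0.263 between it and that PAX7+ library. Cells with PAX7 induced at the time, under the wrong name, are nevertheless argued against by its 2.18 TPM of PAX7, and a myocyte library by its sarcomere genes, which lay a median of −4.62 log2 units from the lowest myocyte library. A smaller share of pluripotent cells alone is argued against too, because cardiac genes were lower, by a median of −2.19 log2 units, while smooth muscle genes were higher, by 1.43. A different course of differentiation in that library may remain as an explanation, as may a library from elsewhere, and neither was tested.

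PAX7 peaks were more frequent near genes that rose, and at day 30 also near genes that fell (odds ratio 1.42, against 1.30 for those that rose, both unmatched). The genes that fell at day 30 were longer than those not called (median 33024 against 28512 bp), so the 1.42 may include an effect of length. The odds ratios below are of genes that rose, with length and expression matched separately. Gene length as the whole cause is argued against at days 14 and 23, where odds ratios against genes of like length were 1.35 and 1.31, and expression level likewise, with 1.55 and 1.37 against genes of like expression. At day 30 the odds ratio was 1.35 against genes of like expression but 1.07 against genes of like length, so length can account for that increase. Chromatin that is open in these cells stays possible as a cause at days 14 and 23, untested here.

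Pluripotency genes were lower in sorted PAX7+ cells at day 14, by a median of −1.81 log2 units. The sort could have left out pluripotent epithelial cells. The median of the epithelial list was −0.16. EPCAM, which such cells carry, stood at 650.2 ± 143 TPM in sorted and 694 ± 79.1 TPM in unsorted cells (n = 4 each). Because EPCAM was high in both groups, these values cannot decide whether the sort left such cells out. Sorting and induction cannot be told apart, because no sorted untreated or unsorted induced cells were measured.

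Among other groupings of the same libraries, none run called as many genes as the real one at days 23 and 30 or for PAX7+ cells over time. This excludes a random labelling of libraries taken as independent. The design text does not say that they came from separate differentiations, so it does not exclude chance more widely. The real grouping gave 3375 genes at day 23 (highest other 828, 1 of 56 groupings as large) and 4928 at day 30 (1647, 1 of 100). It gave 3186 for PAX7+ cells over time (1261, 1 of 100). The count at day 23 was 2048 without replicate 2 of the untreated cells and 1919 with only the 2 groups in the fit. That for PAX7+ cells over time was 2033 without replicate 1 of day 14. For untreated cells over time it gave 1577 (1062, 1 of 35, the smallest share these groupings can give). That share is below 0.05, with the same limit, but the count was 99 without replicate 1 of day 23. It was 399 and 404 without replicate 1 or 2 of day 14 and 2824 without replicate 3 of day 23. With only these 2 groups in the fit limma called 0 genes (2628 at an unadjusted p below 0.05), so this count is weak evidence of a change. At day 14 the real grouping gave 3082 genes (highest other 70, 1 of 35), a share below 0.05 over all 35 groupings, with the same limit. Numbers pair these libraries, and the 8 groupings that part all 4 pairs, the real one included, are too few for a share under 0.05, with 0 genes as the highest other. Chance cannot be excluded for the number of lists called, which was 8 at day 14 (highest other 20, 16 of 35 groupings as large), 13 at day 23 (16, 7 of 56), and 11 at day 30 (16, 23 of 100). It was 10 for PAX7+ cells over time (16, 34 of 100), 7 for untreated cells over time (14, 17 of 35) and 8 for the difference of effects (16, 56 of 100).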
